A study of Mus musculus with 32 samples.

How the data were processed

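RNA-seq and ATAC-seq were measured in AM, IM, iMo and pMo sorted from the lungs of C57BL6J and DBA2J mice, with 2 libraries of each kind per cell type and strain. Per the submitters' protocol, lungs were dissociated at body temperature, and cells were stained for CD45, F4/80, CD11c, CD11b, CD64, Ly6c, Ly6g and SiglecF before the sort, and polyA RNA was sequenced by a strand-specific method. The labels call the iMo monocytes in one field and macrophages in another, and the name monocytes is used here. The authors' table gives RNA levels as TPM per gene for 24940 genes. The deposited ATAC files give, for each cell type and strain, 1 list of peaks made from 2 libraries, with a score per peak whose scale is not given in the sources used here. Per the submitters' processing notes the genome build was mm10 and the tools were STAR, Bowtie and HOMER, without versions or roles. Reads and counts were not analysed here, so depth per library is unknown and precision is known only from the spread between libraries.

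Libraries were grouped by cell type and strain as labelled. Replicate numbers were not used to pair samples, since the residuals of libraries with the same number correlated little (28 pairs of groups, median 0.02, from -0.07 to 0.20, 5 of them over 0.1). Pairs of groups across strains, which cannot share an animal, are among these, so pairing within a strain was not tested on its own. Gene levels were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, in 1 model with a mean for each of the 8 groups (8 residual degrees of freedom) and eBayes with a mean-variance trend. The 12277 genes with a mean of at least 1 TPM over the 16 libraries were tested. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The contrasts were AM minus IM, iMo minus pMo, both macrophages minus both monocytes, DBA2J minus C57BL6J averaged over the cell types and within each, and an F-test of the strain by cell type interaction. A signature gene of a type had an adjusted p under 0.05 and a log2 difference of at least 1 against each of the other 3 types.

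Gene lists were written before the data were examined, as were the model, thresholds, comparisons and most alternatives. Of 32 lists 30 had at least 5 tested members and entered limma's camera test with a preset correlation of 0.01, adjusted over the lists of a contrast. The same test with the correlation estimated from the data, and limma's fry, were the alternatives. Eosinophil and mast cell markers and sex-linked genes had too few tested members and are given as levels. Counts of list members use the adjustment over all genes, and beside them, where they differ, the adjustment over the list alone.

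Single genes were named by a fixed rule. Per contrast these are the 10 largest differences in each direction among called genes with at least 10 TPM in the higher group and no overlap between libraries, without predicted genes and segments of antigen receptors. Added to them are up to 4 called members of each list, all members of the sort panel, sex-linked and known-variant lists, and the 10 interaction genes with the largest range. Not all genes that the rule allows are printed, and some are not reported here. Genes given as heads of signatures, with Spn and Ace, were chosen after their values were seen.

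Peaks were compared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Overlap of 2 peak sets was the Jaccard index in base pairs, and its excess within cell types was tested over all 24 assignments of cell types to the DBA2J sets. A type-specific peak was found in both strains and overlapped no peak of another type by 1 bp or more. Peaks were assigned to the nearest transcription start within 100 kb, and the expression of the assigned genes was tested with camera and an estimated correlation. For each type up to 3 of the best-scored specific peaks near a named gene are given.

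The fits were tested on simulated data of 12277 genes with 200 changed, where a log2 difference of 2 was recovered in 78.7% to 96.7% of genes over the contrasts of 2 groups, and in 63.0% by the interaction test when it lay in 1 group. Within one cell type a difference of 1 was recovered in 27.0% to 40.0%, so that many such differences would be missed. Every group was simulated with the same spread per gene. In the data the SD of the log2 difference between replicates ran from 0.414 in C57BL6J AM to 0.885 in C57BL6J IM. Recovery and false calls in groups of unequal spread were therefore not tested. Alternatives covered the pseudocount, filter, scaling, variance trend, replicate number as a block, libraries in the fit, fold minimum, single strains, leaving out each library, list test, and peak selection and assignment. Removing the 2 ribosomal entries, a second peak score, a narrower gene background for peaks, leaving out both C57BL6J IM libraries, and leaving out RNA libraries in the peak comparison were added after the data were seen.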

Results

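The series holds RNA-seq and ATAC-seq of 4 kinds of mononuclear phagocyte sorted from the lungs of C57BL6J and DBA2J mice, which are inbred laboratory strains. The labels name alveolar macrophages (AM, resident in the airspaces), interstitial macrophages (IM, resident in the lung tissue), inflammatory monocytes (iMo) and patrolling monocytes (pMo). For every cell type and strain there were 2 RNA-seq libraries and 2 ATAC-seq libraries, 16 of each kind in 8 groups. All mice are labelled as untreated, although the series title speaks of activated phagocytes. RNA levels were given as TPM for 24940 genes, and open chromatin as 1 list of reproducible peaks per group. The read depth of the libraries is unknown, since TPM keeps no counts. No label says that replicates came from separate animals, so p-values measure the spread between these samples only.

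The 2 ribosomal entries Rn45s and Mir6236 took a share of the nominal TPM total that differed between cell types, 53.4% ± 1.66 in AM, 29.8% ± 1.28 in IM, 21.2% ± 7.60 in iMo and 35.1% ± 5.73 in pMo (SD, n = 4). The genes given summed to less than that total, from 632076 to 822130 TPM per library. Of this sum the 2 entries took 22.6% to 67.6%. The level of every other gene in a library depends on that share, and the median log2 difference of all 12277 tested genes was -0.68 between AM and IM. More genes were listed above 1 TPM in IM (12347 ± 191) than in AM (10881 ± 269), iMo (11033 ± 145) and pMo (11134 ± 204). The first principal component held 43.8% of the variance and set AM apart from the other types, and the second held 17.9% and set IM apart from both monocytes. The replicates of a group correlated with r from 0.877 in C57BL6J IM to 0.974 in C57BL6J AM across genes. Xist, the transcript of the silenced X chromosome, was at or below 0.363 TPM in every library and Ddx3y, on the Y chromosome, at or above 6.73 TPM, so that the libraries of both strains carried RNA of male cells.

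The comparison of AM with IM addresses what separates the resident macrophages of the airspaces from those of the tissue. AM had higher levels of Krt79, a keratin gene (152 ± 19.3 TPM in AM against 13.6 ± 10.8 in IM, mean ± SD, n = 4 each), of Fabp1, a fatty acid binding protein, of Cidec, a lipid droplet protein, and of Siglecf, the surface lectin used in the sort. IM had higher levels of C1qa, a chain of complement C1q (1061 ± 525 against 0.970 ± 0.461 TPM), of the transcription factor Maf, and of Cx3cr1, the fractalkine receptor. MHC class II transcripts were far more abundant in IM, where H2-Aa averaged 1595 TPM against 31.8 in AM. In all, limma called 8624 genes at an adjusted p under 0.05, 1128 higher and 7496 lower in AM, and 4575 of them differed at least 2-fold. That split follows the scaling. With median-of-ratios scaling the median difference of all genes became 0.06 and the calls 4064 higher and 3534 lower, with quantile normalization 3993 and 3457, and without the ribosomal entries 2563 and 4957.

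Among single genes, the log2 difference between AM and IM was 3.91 ± 0.36 (± SE) for Krt19, 3.91 ± 0.21 for the peroxisomal thiolase Acaa1b, 3.89 ± 0.45 for the short-chain fatty acid receptor Ffar2, 3.64 ± 0.31 for Krt79, 3.62 ± 0.22 for Fabp1, 3.48 ± 0.26 for Cidec and 3.28 ± 0.27 for Plet1. On the IM side it was -9.58 ± 0.37 for Retnla, a secreted resistin-like protein (0.0735 against 910.4 TPM), and -7.50 ± 0.22 for Maf. Their adjusted p ranged from 4.0e-09 for Retnla to 2.2e-05 for Ffar2.

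Of the 20 alveolar macrophage markers fixed beforehand, 19 were higher in AM (adjusted p = 3.8e-22; 0.0569 with an estimated correlation). All 18 tested interstitial macrophage markers were lower in AM (adjusted p = 1.2e-07; 0.252 with an estimated correlation). Both lists hold genes close to the sort and are not independent of it. Of 23 genes of lipid uptake and catabolism 14 were higher and 6 lower in AM, and 14 and 8 when adjusted over the list alone (adjusted p = 1.6e-07; 0.252 with an estimated correlation). They included Angptl4, an inhibitor of lipoprotein lipase (log2 3.17 ± 0.33), and Abcg1, a cholesterol exporter (2.46 ± 0.20), both higher, and the scavenger receptor Msr1 (-3.20 ± 0.21), lower. Of 21 cell cycle genes 6 were higher in AM, 4 adjusted over the list alone, Rrm2 of nucleotide synthesis among them (1.41 ± 0.17), and none was lower (adjusted p = 9.8e-06; 0.176 with an estimated correlation). With median-of-ratios scaling 20 of these 21 were called higher.

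Immune response lists were lower in AM. The IM libraries also had higher levels of neutrophil and B cell markers, given below. The immune lists are therefore not separated here from RNA of other cells in the IM libraries. All 24 interferon-stimulated genes were lower, such as Oas2 (-5.50 ± 0.23) and the regulator Irf7 (-4.91 ± 0.22), with adjusted p = 9.8e-06 for the list and 0.428 with an estimated correlation. Of 11 genes of MHC class II presentation 10 were lower, H2-Aa at -5.83 ± 0.17 and Cd74 at -5.07 ± 0.18, and of 13 complement genes 12 were lower and 1 higher. Lower in AM were also 15 of 18 chemokine receptor and trafficking genes, among them Ccr2 (-6.85 ± 0.27) and Cx3cr1 (-6.97 ± 0.13), 21 of 23 genes of Toll-like receptor signalling, with the DNA sensor Tlr9 at -6.37 ± 0.16, and 17 of 21 NF-kB response genes, with the cytokine Il1b at -5.16 ± 0.23. In each of these 3 lists 1 gene was higher. Of the immediate early and dissociation genes 17 of 21 were lower and 1 higher, with Egr1 at -4.12 ± 0.34. The markers of both monocytes were lower too, 15 of 15 for patrolling monocytes and 12 of 13 for classical monocytes with 1 higher. The counts adjusted over each list alone were the same for these 9 lists. Part of them follows the scaling. With median-of-ratios scaling the calls were 13 lower and 3 higher for Toll-like receptor signalling, 12 and 4 for NF-kB, 10 and 2 for immediate early genes, 13 and 3 for chemokine receptors, 10 and 2 for complement, 9 and 2 for MHC class II and 22 and 0 for interferon-stimulated genes. All these lists still passed there (highest adjusted p = 0.0140). Apart from the interferon list, adjusted p ran from 1.0e-04 (patrolling monocyte markers) over 3.7e-04 (classical monocyte markers and MHC class II), 0.00109 (complement), 0.00367 (chemokine receptors), 0.00629 (Toll-like receptors) and 0.0277 (immediate early) to 0.0286 (NF-kB). With an estimated correlation the adjusted p was 0.417, 0.252 (classical monocyte markers), 0.338 (MHC class II), 0.338, 0.417, 0.450, 0.414 and 0.423.

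Markers of other cells went with the IM libraries. All 8 tested neutrophil markers were lower in AM, with S100a8 at 1302 ± 144 TPM in IM against 8.62 ± 2.79 in AM (log2 -7.12 ± 0.30) and the gelatinase Mmp9 at -8.23 ± 0.17 (adjusted p = 2.4e-05; 0.0569 with an estimated correlation). Ly6g, a neutrophil marker whose protein was stained in the sort, averaged 1.12 ± 0.781 TPM in IM (SD, n = 4). All 8 B cell markers were lower in AM (adjusted p = 0.0258 for the list, 0.536 with an estimated correlation). Of 9 endothelial markers 8 were lower, Pecam1 at -2.33 ± 0.25, but only 3 with median-of-ratios scaling and 2 with quantile normalization, and the list did not pass (adjusted p = 0.468). Lower without passing as lists were also 8 of 9 dendritic cell markers with Ffar2 higher (adjusted p = 0.0545), 6 of 12 T and NK cell markers with Cd2 higher (0.935), 4 of 7 epithelial markers with 2 higher (0.270; the test pointed up while the median was negative) and 3 of 5 fibroblast markers (0.881). Of 5 erythroid genes 1 was lower, none adjusted over the list alone, while the test of the list pointed up (adjusted p = 0.0230; 0.417 with an estimated correlation; 0.353 with median-of-ratios scaling).

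For several metabolic lists the direction depended on the scaling. Of 30 oxidative phosphorylation genes 5 were higher and 9 lower in AM as deposited, but 21 and 0 with median-of-ratios scaling, and the test, which compares with all other genes, pointed up (adjusted p = 9.9e-04; 0.417 with an estimated correlation). Of 26 lysosomal genes 7 were higher, such as the proteases Ctsk (2.21 ± 0.30) and Ctsd (1.77 ± 0.15), and 8 lower, such as Lgmn (-2.20 ± 0.11), against 21 and 3 with median-of-ratios scaling (adjusted p = 0.00131; 0.423 with an estimated correlation). Adjusted over the list alone the counts as deposited were 5 and 7 for oxidative phosphorylation and 7 and 7 for the lysosome. The cholesterol synthesis list (2 higher, 11 lower of 17; 6 and 1 with median-of-ratios scaling), glycolysis (1 and 10 of 17; 8 and 4) and MHC class I presentation (0 and 11 of 13; 4 and 4) did not pass, with adjusted p = 0.767, 0.934 and 0.102. The alternative activation genes (1 higher, 8 lower of 12; adjusted p = 0.216), lineage transcription factors (10 and 12 of 23; 0.430) and sort panel genes (2 and 6 of 8; 0.767) did not pass either. Within the sort panel Siglecf (2.95 ± 0.31) and Itgax, which codes for CD11c (1.10 ± 0.18), were higher in AM. Itgam, which codes for CD11b (-6.52 ± 0.14), and Ly6c2 (-5.93 ± 0.38) were lower.

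**Figure D1:**
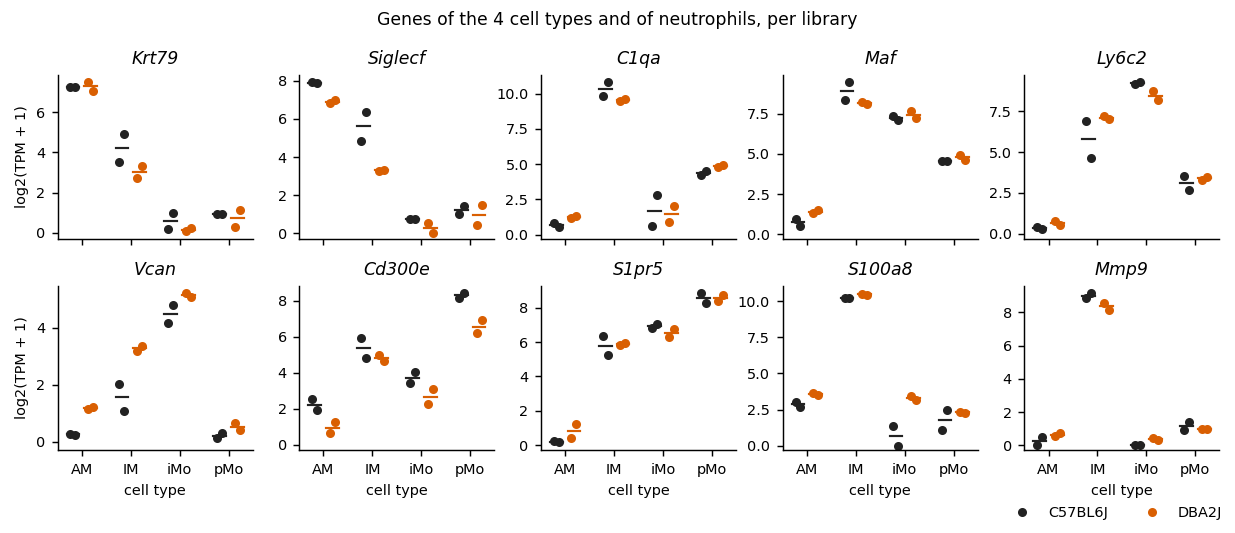
Level of 10 genes in each RNA library, as log2(TPM + 1), by cell type (x axis) and strain (colour); points are libraries and bars the mean of 2. S100a8 and Mmp9 stand high in all 4 IM libraries, S100a8 between 1167 and 1467 TPM there and at or below 11.4 TPM elsewhere.

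The monocyte comparison asks what separates the recruited from the patrolling kind. Ly6c2, the surface marker that defines inflammatory monocytes, averaged 471 ± 151 TPM in iMo and 8.80 ± 2.36 in pMo (SD, n = 4 each). Its log2 difference of 5.57 ± 0.38 had an adjusted p of 3.5e-06. The chemokine receptor Ccr2 (2.73 ± 0.27), fibronectin Fn1 (4.47 ± 0.13), the clotting factor subunit F13a1 (4.49 ± 0.19), the proteoglycan Vcan (4.45 ± 0.21), the collagenase Mmp8 (5.07 ± 0.22), Cd177 (4.54 ± 0.21) and the chemokine Cxcl10 (4.14 ± 0.41) were higher in iMo as well. pMo had higher levels of the receptor Cd300e (207 ± 131 against 9.14 ± 4.93 TPM, log2 -4.23 ± 0.31), the MAP kinase phosphatase Dusp16 (-3.44 ± 0.27), Itgax (-2.93 ± 0.18), the enolase Eno3 (-2.55 ± 0.24), the fatty acid binding protein Fabp4 (-3.19 ± 0.28), the nuclear receptor Pparg (-2.70 ± 0.21), the scavenger receptor Cd36 (-2.57 ± 0.26), the adrenergic receptor Adrb1 (-3.58 ± 0.37) and the sphingosine phosphate receptor S1pr5 (-1.82 ± 0.25). limma called 3105 genes, 2324 higher and 781 lower in iMo, of which 1030 differed at least 2-fold. The split was 1557 and 1555 with median-of-ratios scaling, 1467 and 1317 with quantile normalization and 1141 and 1822 without the ribosomal entries. The median difference of all genes was 0.13 as deposited and -0.02 with median-of-ratios scaling.

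Of 13 classical monocyte markers 12 were higher in iMo (adjusted p = 5.4e-14; 0.0260 with an estimated correlation), and of 15 patrolling monocyte markers 13 were lower, 14 adjusted over the list alone (adjusted p = 1.1e-14; 0.319 with an estimated correlation). The sort used Ly6c, so neither list is independent of it. Of 24 interferon-stimulated genes 23 were higher in iMo, among them Isg15 (2.68 ± 0.49; 77.8 against 11.9 TPM), Ifit3 (2.68 ± 0.53) and Rsad2 (2.31 ± 0.31), and none was lower (adjusted p = 2.7e-11; 0.394 with an estimated correlation). Of 23 genes of Toll-like receptor signalling 9 were higher and none lower, with the flagellin receptor Tlr5 at 2.45 ± 0.17 (adjusted p = 0.0263; 0.665 with an estimated correlation). With median-of-ratios scaling 6 were higher and 2 lower, and the list passed with none of the 3 other scalings (adjusted p = 0.0746, 0.249 with quantile normalization and 0.0843 without the ribosomal entries). Of 30 oxidative phosphorylation genes 11 were higher, 13 adjusted over the list alone, but 2 with median-of-ratios scaling (adjusted p = 0.0120; 0.617 with an estimated correlation). That list did not pass with the other scalings either (adjusted p = 0.0746, 0.173 and 0.0818 in the same order).

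Lower in iMo than in pMo were 6 of 20 alveolar macrophage markers, with 2 higher (7 and 2 adjusted over the list alone; adjusted p = 1.3e-05), and 6 of 18 interstitial macrophage markers, with 2 higher, such as C1qa (-3.06 ± 0.41) and Maf (2.67 ± 0.22) on either side (adjusted p = 3.2e-04). NF-kB response genes had 6 lower, Nfkbiz (-1.85 ± 0.18) and Cd83 (-2.61 ± 0.16) among them, and 2 higher of 21 (adjusted p = 0.00127). Cell cycle genes had 3 lower and 1 higher of 21 (adjusted p = 0.00183; 0.0904 with quantile normalization). Lower too were markers of other cells, 1 of 8 for B cells (Cd79a, -1.29 ± 0.33; adjusted p = 0.00145) and 1 of 12 for T and NK cells (Il7r, -0.53 ± 0.17, none adjusted over the list alone; adjusted p = 7.4e-04). With median-of-ratios scaling 7 of 21 cell cycle, 2 of 8 B cell and 5 of 12 T and NK cell genes were lower. With an estimated correlation the adjusted p of these 6 lists was 0.394 for alveolar, 0.447 for interstitial macrophage markers, 0.394 for NF-kB, 0.394 for the cell cycle, 0.617 for B cells and 0.394 for T and NK cells. The other 19 lists did not pass. They included the lysosome (10 higher and 3 lower of 26, 12 and 4 alone; adjusted p = 0.168; 6 and 6 with quantile normalization), cholesterol synthesis (7 higher of 17; 0.110; 4 higher and 2 lower without the ribosomal entries) and lineage transcription factors (10 and 6 of 23, 11 and 6 alone, Cebpa higher at 2.38 ± 0.27; 0.577).

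The comparison of both macrophages with both monocytes sets the mean of 2 types against the mean of 2 others, so that 1 type alone can carry a call. Of the 6726 genes called, 1104 kept all macrophage libraries apart from all monocyte libraries, 613 higher and 491 lower. Spp1, a secreted phosphoprotein, had a log2 difference of 5.73 ± 0.14 (291 against 2.85 TPM, means of 8 libraries each). The ribonuclease Ear1 (6.49 ± 0.45), the proton pump subunit Atp6v0d2 (5.10 ± 0.13), the leukotriene synthase Ltc4s (5.10 ± 0.37), the mannose receptor Mrc1 (4.21 ± 0.16), cathepsins Ctsk (4.26 ± 0.21) and Ctsd (3.29 ± 0.11) and the transcription factors Bhlhe41 (4.19 ± 0.20) and Egr2 (3.68 ± 0.14) were higher in macrophages. Monocytes had higher levels of Ifitm6 (-4.98 ± 0.16), S1pr5 (-4.48 ± 0.17), Plac8 (-4.01 ± 0.14), the transcription factor Pou2f2 (-3.98 ± 0.16), Cx3cr1 (-3.90 ± 0.09), the adhesion receptor Adgre5 (-3.71 ± 0.11) and Nr4a1, a nuclear receptor needed by patrolling monocytes (-3.51 ± 0.15). limma called 6726 genes, 2324 higher and 4402 lower in macrophages, and 2074 at least 2-fold. With median-of-ratios scaling the split was 3224 and 3651, with quantile normalization 2862 and 3776, and without the ribosomal entries 3631 and 2728. The median difference of all genes was -0.17 as deposited.

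All 24 interferon-stimulated genes were lower in the macrophage mean, Irf7 at -3.38 ± 0.15 and Mx1 at -2.92 ± 0.32, and 12 of 13 genes of MHC class I presentation, H2-K1 at -1.20 ± 0.10 and its regulator Nlrc5 at -2.10 ± 0.12. All 24 interferon-stimulated genes were also lower in AM than in IM, and 23 were higher in iMo than in pMo. The calls on the means therefore do not place IM below pMo. Higher in macrophages were 16 of 21 cell cycle genes, 18 adjusted over the list alone, such as Rrm2 (2.06 ± 0.12) and Top2a (1.73 ± 0.17), 16 of 23 lipid genes with 3 lower, and 19 of 20 alveolar macrophage markers. The macrophage mean was also higher for 13 of 18 interstitial macrophage markers with 4 lower, 9 of 13 complement genes with 2 lower, 7 of 12 alternative activation genes with 2 lower and 11 of 26 lysosomal genes with 7 lower (19 and 4 without the ribosomal entries). Of these lists, all 18 interstitial macrophage, 12 of 13 complement and 8 of 12 alternative activation genes were lower in AM than in IM, and C1qa averaged 24.1 ± 5.46 TPM in pMo, above AM. Patrolling monocyte markers were lower in 14 of 15 and classical ones in 9 of 13, with 1 and 2 higher. Markers of other cells were higher in the macrophage mean, 7 of 8 for neutrophils with 1 lower (adjusted p = 9.2e-06), 8 of 9 for endothelium with 1 lower (0.00201) and 4 of 7 for epithelium (0.0283; 0.0660 with median-of-ratios scaling). Adjusted p for the other lists was 2.4e-16 (alveolar), 2.8e-07 (interferon), 2.8e-07 (cell cycle), 3.3e-07 (patrolling), 6.0e-07 (lipid), 8.0e-05 (MHC class I), 9.6e-05 (interstitial), 0.00101 (complement), 0.00511 (alternative activation), 0.0136 (lysosome) and 0.0283 (classical). With an estimated correlation none of the 14 lists passed, the lowest adjusted p = 0.0757 (neutrophil markers, with an estimated correlation) and the highest adjusted p = 0.567 (lysosome, likewise).

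Genes higher in 1 cell type than in each of the other 3, by at least 2-fold, numbered 369 for AM, 516 for IM, 134 for iMo and 109 for pMo. The AM set was led by Krt19, Acaa1b and Ffar2 and held 16 of 20 alveolar macrophage markers, 8 of 23 lipid genes and 4 of 21 cell cycle genes. The IM set held 13 of 18 interstitial macrophage markers and 8 of 13 complement genes, but was led by the neutrophil genes S100a9, Mmp9, Retnlg and S100a8 and held 8 of 8 neutrophil, 7 of 9 endothelial, 4 of 12 T and NK cell and 2 of 5 fibroblast markers. Cd209f, Cxcl13, Pf4, Lyve1, Stab1 and Ccl8 followed in it. The iMo set was led by Cd177, Vcan and Ly6c2 and held 10 of 24 interferon-stimulated genes. The pMo set held 11 of 15 patrolling monocyte markers, among them Spn (1584 TPM against 426.4 in iMo) and Ace, the angiotensin-converting enzyme (1362 against 422.4 TPM). With median-of-ratios scaling the AM set grew to 914 genes and the IM set fell to 290.

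The strain comparison, DBA2J minus C57BL6J averaged over the cell types, called 1434 genes, 537 higher and 897 lower in DBA2J, and 360 at least 2-fold. The largest difference was in H2-Ea-ps (mm10 chromosome 17, 34342212 to 34344645), the MHC class II alpha chain gene whose promoter is deleted in C57BL6J, at a log2 difference of 7.47 ± 0.12 (678 against 1.06 TPM, adjusted p = 2.0e-11, 8 libraries per strain). Also higher in DBA2J were the interferon-inducible gene Ifi202b (chromosome 1, 173962569 to 173982844; 4.39 ± 0.14), the scavenger receptor Stab2 (3.76 ± 0.09), the potassium channel subunit Kcne3 (3.50 ± 0.09) and the chemokine receptor Ccr2 (0.83 ± 0.19). Lower in DBA2J were Trim12a (chromosome 7, 104299897 to 104315495; -4.62 ± 0.14), its neighbour Trim30d (-2.84 ± 0.16), Mndal (-3.34 ± 0.20), the inflammasome pseudogene Nlrp1c-ps (-3.17 ± 0.12), glutathione reductase Gsr (-2.69 ± 0.11), the chaperone Hspa8 (-2.20 ± 0.19), the chitinase-like Chil3 (-1.88 ± 0.16) and the chemokine receptor Cxcr4 (-1.08 ± 0.11). Among loci with variants known between these strains, Glo1, duplicated in DBA2J, was higher (0.91 ± 0.11), and Gpnmb and Klrd1, both disrupted in DBA2J, were lower (-1.60 ± 0.23 and -1.38 ± 0.31). Klrd1 is a gene of NK cells. It was lower in pMo (-2.69 ± 0.62), missed the threshold in iMo (-2.23 ± 0.62, adjusted p = 0.0891) and stood at 0.08 ± 0.62 in AM, while the granzyme Gzma was lower in pMo (-2.49 ± 0.56) and iMo (-2.98 ± 0.56), so the Klrd1 variant is not separated here from a difference in NK cell transcripts. Nnt, which carries a deletion in C57BL6J, did not differ past the threshold (-0.23 ± 0.15, adjusted p = 0.411), and the list of these 5 loci did not pass (adjusted p = 0.259, with a negative median and a positive mean). H2-Q1 (5.15 ± 0.15), H2-Q2 (4.56 ± 0.31), Rpl38 (3.81 ± 0.21), Rpl29 (-4.02 ± 0.32) and Rps2 (-2.64 ± 0.10) passed too. They belong to families with near-identical copies, and since reads were not analysed here their values are uncertain. Genes of other families, such as Trim12a and Trim30d, were not examined for shared reads either. The split of calls was 971 higher and 955 lower with median-of-ratios scaling, 900 and 937 with quantile normalization and 799 and 808 without the ribosomal entries.

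Immediate early and dissociation genes were lower in DBA2J, 12 of 21 and 13 adjusted over the list alone, with none higher (adjusted p = 3.3e-06; 0.163 with an estimated correlation). They included the heat shock genes Hspa1b (-2.49 ± 0.57) and Hspa1a (-2.42 ± 0.58), which are near-identical copies, the phosphatase Dusp1 (-1.37 ± 0.16; 162 against 344 TPM) and Fosb (-1.31 ± 0.22). Of 13 classical monocyte markers 4 were higher, 7 adjusted over the list alone, with the coagulation factor F5 at 1.74 ± 0.14 (adjusted p = 1.0e-04; 0.303 with an estimated correlation). Chemokine receptor and trafficking genes had 4 higher and 1 lower of 18 (5 and 1 alone; adjusted p = 0.00630; 0.692 with an estimated correlation). Alveolar macrophage markers had 5 lower, Marco (-1.38 ± 0.34) among them, and 1 higher of 20 (10 and 1 alone; adjusted p = 0.0210; 0.755 with an estimated correlation). Lysosomal genes had 4 lower of 26 (6 alone; adjusted p = 0.00630; 0.755 with an estimated correlation), the cell cycle 2 lower of 21 (2 alone; 0.00630; 0.488 with an estimated correlation) and oxidative phosphorylation 2 lower of 30 (0 alone; 0.0254; 0.755 with an estimated correlation). Markers of other cells differed as well. B cell markers were higher in DBA2J, 3 of 8 and 7 adjusted over the list alone (adjusted p = 1.0e-04; 0.645 with an estimated correlation), neutrophil markers in 2 of 8 (3 alone; 0.0352; 0.388 with an estimated correlation), and epithelial markers were lower in 5 of 7 (5 alone; 0.00502; 0.342 with an estimated correlation). With median-of-ratios scaling neutrophil markers and oxidative phosphorylation no longer passed (adjusted p = 0.111 and 0.0592). The other 20 lists did not pass. The T and NK list had 3 lower and 1 higher of 12 (4 and 2 alone), with Prf1 at -1.49 ± 0.31 and Gzma at -1.40 ± 0.28 (adjusted p = 0.521).

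**Figure D2:**
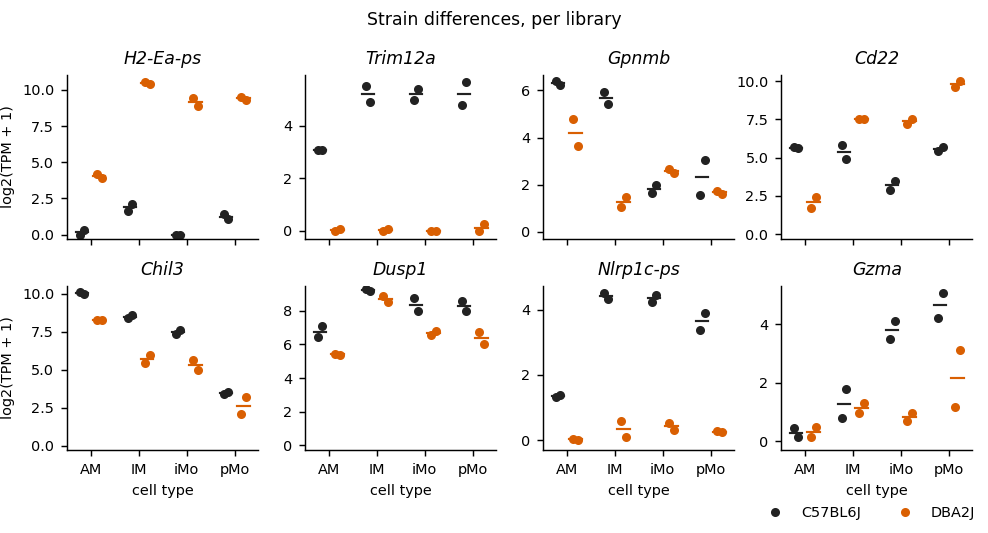
Level of 8 genes that differ between strains, as log2(TPM + 1) in each RNA library, by cell type (x axis) and strain (colour); points are libraries and bars the mean of 2. H2-Ea-ps is higher and Trim12a lower in the DBA2J libraries of all 4 types, while Cd22 is lower in DBA2J AM and higher in the other types.

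Within AM, 403 genes were called, 244 higher and 159 lower in DBA2J. The matricellular gene Nov (5.42 ± 0.26; 68.0 against 0.615 TPM, n = 2 each), the elastase Mmp12 (2.55 ± 0.29), Msr1 (2.22 ± 0.30) and the chemokine Ccl3 (1.99 ± 0.47) were higher in DBA2J AM. The ion channel Mcoln3 (-5.04 ± 0.27), the scavenger receptor Marco (-3.13 ± 0.67), Epcam (-3.14 ± 0.56), Tlr5 (-2.26 ± 0.23), Gpnmb (-2.11 ± 0.45) and Chil3 (-1.77 ± 0.33; 312 against 1065 TPM) were lower. Genes of MHC class II presentation were lower, 4 of 11 and 5 adjusted over the list alone, with Cd74 at -1.86 ± 0.26 and H2-Aa at -1.59 ± 0.24 (adjusted p = 6.2e-07; 0.256 with an estimated correlation). NF-kB response genes were higher, 3 of 21 and 9 adjusted over the list alone (adjusted p = 3.9e-05; 0.272 with an estimated correlation). The cell cycle list moved down without any of its 21 genes being called by limma (unadjusted p under 0.05 for 5 of them; adjusted p = 5.3e-07 for the list, 0.216 with an estimated correlation). Interstitial macrophage markers were higher in 2 of 18 (4 alone) and endothelial markers in 1 of 9 (7 alone). These were among 15 lists past camera's preset test (adjusted p = 1.7e-04 and 1.7e-05), of which none passed with an estimated correlation (lowest adjusted p = 0.216, with an estimated correlation). Other cells' markers moved in the same libraries. Epithelial markers were lower in 1 of 7 (2 alone), and dendritic cell (3 of 9 alone), fibroblast (2 of 5 alone) and erythroid lists (0 of 5 alone) lay higher with 0 called by limma (unadjusted p under 0.05 for 4, 2 and 0). Their adjusted p was 1.7e-04, 0.00788, 0.0392 and 0.0425 (0.216, 0.387, 0.467 and 0.467 with an estimated correlation). Leaving out any 1 of the 4 AM libraries lowered the count of genes to between 186 and 234, and a fit of the 4 AM libraries alone gave 697. The split was 336 higher and 310 lower with median-of-ratios scaling, where the lysosome and immediate early lists no longer passed (adjusted p = 0.227 and 0.0791).

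Within IM, 1290 genes were called, 463 higher and 827 lower in DBA2J. The lipoxygenase Alox15 (4.50 ± 0.59; 97.8 against 5.17 TPM, n = 2 each), Stab2 (4.52 ± 0.17), F5 (3.23 ± 0.28), Isg15 (4.00 ± 0.69), Rsad2 (1.73 ± 0.43), and Ccr2 (1.33 ± 0.38) were higher in DBA2J IM. Gpnmb (-4.41 ± 0.45), the matrix protein Cyr61 (-3.52 ± 0.65), Chil3 (-2.78 ± 0.33), Stab1 (-2.14 ± 0.32; 92.4 against 428 TPM), Siglecf (-2.30 ± 0.44) and the cathepsins Ctsk (-2.67 ± 0.43) and Ctsd (-1.36 ± 0.22) were lower. Interferon-stimulated genes were higher, 5 of 24 and 12 adjusted over the list alone (adjusted p = 8.8e-08; 0.598 with an estimated correlation), and classical monocyte markers in 6 of 13, 8 alone (8.1e-06; 0.361 with an estimated correlation). Lysosomal genes were lower in 10 of 26, 13 alone (1.1e-07; 0.539 with an estimated correlation), and interstitial macrophage markers in 4 of 18, 9 alone (1.8e-04; 0.581 with an estimated correlation). Alveolar macrophage markers were lower in 9 of 20 with 1 higher, 12 and 2 alone (2.1e-04; 0.581 with an estimated correlation). Chil3, Siglecf and Ctsk are on that list. Krt79, high in AM, ran from 5.58 to 29.5 TPM in IM, highest in C57BL6J replicate 2. On the first principal component, which set AM apart at negative values, that library lay at 6.29 and the other IM libraries at 30.0, 42.5 and 38.5. The alveolar genes are therefore not separated here from AM RNA in that library. The iMo signature held 10 of the 24 interferon-stimulated genes and 6 of the 13 classical monocyte markers. Higher levels of both lists are therefore not separated here from monocyte RNA in the DBA2J IM libraries. Markers of other cells differed in the IM libraries too. Neutrophil markers were higher in 2 of 8 (4 alone, with 1 lower; adjusted p = 0.0458; 0.539 with an estimated correlation), with Ngp at 2.49 ± 0.44, and endothelial, epithelial and fibroblast markers lower in 1 of 9, 2 of 7 and 1 of 5 (4, 3 and 2 alone; adjusted p = 0.00847, 0.0336 and 0.0458; 0.673, 0.539 and 0.625 with an estimated correlation). With median-of-ratios scaling the neutrophil and fibroblast lists no longer passed (adjusted p = 0.0635 and 0.0635). With quantile normalization the epithelial list did not pass either (adjusted p = 0.112). The C57BL6J replicates of IM differed most from each other of all groups, with summed B cell marker levels of 327.6 and 79.6 TPM. The count of genes was 492 without DBA2J replicate 1, 559 without C57BL6J replicate 2, 823 without DBA2J replicate 2, and 61 when only the 4 IM libraries entered the fit. The split was 706 higher and 888 lower with median-of-ratios scaling and 982 and 1180 with quantile normalization. Lists past the test fell from 14 to 7 without C57BL6J replicate 2 and without DBA2J replicate 1.

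Within iMo, 426 genes were called, 161 higher and 265 lower in DBA2J. The chitinase-like Chil1 (5.56 ± 0.30; 51.2 against 0.0985 TPM, n = 2 each), the adhesion receptor Adgrg5 (4.84 ± 0.22), the folate receptor Folr2 (3.88 ± 0.39), and Ccr1 (1.84 ± 0.28) were higher in DBA2J. Mndal (-5.16 ± 0.39), Ifi213 (-4.23 ± 0.42), the prostaglandin dehydrogenase Hpgd (-3.63 ± 0.43), Chil3 (-2.16 ± 0.33), Cxcr4 (-1.83 ± 0.22), Dusp1 (-1.69 ± 0.31) and the cytokine signal inhibitor Socs3 (-1.33 ± 0.21) were lower. Transcripts of cytotoxic lymphocytes were lower as well, Nkg7 at -3.75 ± 0.88, Gzma at -2.98 ± 0.56 and Prf1 at -2.87 ± 0.62, 3 of 12 T and NK cell markers (6 alone, with 1 higher), although the list did not pass (adjusted p = 0.561). Immediate early genes were lower in 4 of 21, 11 adjusted over the list alone (adjusted p = 2.3e-05; 0.129 with an estimated correlation), and in 2 with median-of-ratios scaling and with quantile normalization. The other 8 lists past the preset test had 0 to 2 genes called each, among them neutrophil markers with S100a8 higher (2.63 ± 0.43), and none passed with an estimated correlation. B cell and erythroid markers, also among the 8, lay higher with 0 called (camera adjusted p = 0.00422 and 0.00285). The B cell list did not pass with quantile normalization (adjusted p = 0.0619). Of the 8 lists glycolysis no longer passed with median-of-ratios scaling (adjusted p = 0.143). Leaving out C57BL6J replicate 2, DBA2J replicate 1 or DBA2J replicate 2 gave 252, 259 and 203 genes, the 4 iMo libraries alone gave 244, and leaving out C57BL6J replicate 1 cut the lists past the test from 9 to 2. The median difference of all genes was -0.14, and with median-of-ratios scaling the split was 269 higher and 245 lower.

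Within pMo, 449 genes were called, 167 higher and 282 lower in DBA2J. The B cell inhibitory receptor Cd22 (4.24 ± 0.32; 911 against 46.9 TPM, n = 2 each), the ATP-gated channel P2rx1 (4.48 ± 0.27), Kcne3 (4.23 ± 0.18) and F5 (2.48 ± 0.28) were higher in DBA2J. Hpgd (-3.43 ± 0.43), the chemokines Ccl4 (-3.15 ± 0.57) and Ccl3 (-2.31 ± 0.47), the granzyme Gzmb (-3.12 ± 0.68), Fos (-2.02 ± 0.41), Dusp1 (-1.91 ± 0.31) and Cxcr4 (-1.79 ± 0.22) were lower. Markers of cytotoxic lymphocytes were lower in the same libraries, Gzma at -2.49 ± 0.56 and Klrb1c at -2.24 ± 0.53, 2 of 12 T and NK cell markers (2 alone), although the list did not pass (adjusted p = 0.351). Immediate early genes were lower in 5 of 21, 11 adjusted over the list alone (adjusted p = 8.5e-05; 0.363 with an estimated correlation), and in 2 with median-of-ratios scaling. B cell markers lay higher as a list, with 0 of 8 called by limma (unadjusted p under 0.05 for 5) and 5 adjusted over the list alone (adjusted p = 6.1e-06; 0.815 with an estimated correlation). MHC class II presentation had 1 of 11 higher, 2 alone with 1 lower (0.0367; 0.815 with an estimated correlation). The count of genes was 191 without C57BL6J replicate 2 and 241 without DBA2J replicate 1, and 156 when only the 4 pMo libraries entered the fit, and 1 list passed without C57BL6J replicate 1. The median difference of all genes was -0.15, and with median-of-ratios scaling the split was 384 higher and 326 lower, and MHC class II did not pass (adjusted p = 0.0535).

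The strain difference itself depended on the cell type for 495 genes by the interaction test. That count ranged from 239 to 833 when 1 library was left out, and was 760 with median-of-ratios scaling, 920 with quantile normalization and 820 without the ribosomal entries. Cd22 (chromosome 7, 30865404 to 30880342) had log2 differences of -3.57 in AM, 2.14 in IM, 4.19 in iMo and 4.24 in pMo (adjusted p = 1.7e-05). H2-M2, an MHC class I-like gene with close relatives, was lower in DBA2J IM (log2 -4.52) and higher in AM, iMo and pMo (3.18, 4.47 and 3.39; adjusted p = 1.7e-05). Nov was higher in DBA2J AM (5.42), IM and pMo (1.14), with 0.20 in iMo, which did not pass (interaction adjusted p = 4.8e-05). Gpnmb was lower in AM and IM (-2.11 and -4.41) with 0.79 in iMo and -0.64 in pMo (adjusted p = 0.00435). H2-Q10, Stap2, Chil1, Plekha6, Wfdc21 and H2-Ea-ps complete the 10 largest ranges. Of the genes called within the types, 1369 were called in 1 type, 268 in 2, 125 in 3 and 72 in 4, of which 68 went the same way in all 4 (38 higher and 30 lower in DBA2J). iMo and pMo shared 97 genes higher and 144 lower in DBA2J, where independent lists of those sizes would share 2.19 and 6.09 (Fisher's exact adjusted p = 1.1e-150 and 2.1e-177), and none went opposite ways. AM and IM shared 70 and 71 (9.20 and 10.7 expected, Fisher's exact adjusted p = 8.7e-43 and 2.9e-41) and 16 went opposite ways. The model uses 1 variance per gene for all types, so calls in different types are not independent. Fisher's exact test assumes that they are, and its p-values here do not measure replication. Genes whose 2 DBA2J libraries lay on one side of both C57BL6J libraries numbered 4325 higher and 2203 lower in AM, 3134 and 3632 in IM, 1304 and 3744 in iMo, and 1618 and 3185 in pMo, where chance alone gives 33.3% of all genes. That share assumes no shift common to all genes. In iMo the ribosomal share was 21.5% and 31.7% in DBA2J against 17.2% and 14.3% in C57BL6J, which lowers every other gene in DBA2J as deposited.

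**Figure D3:**
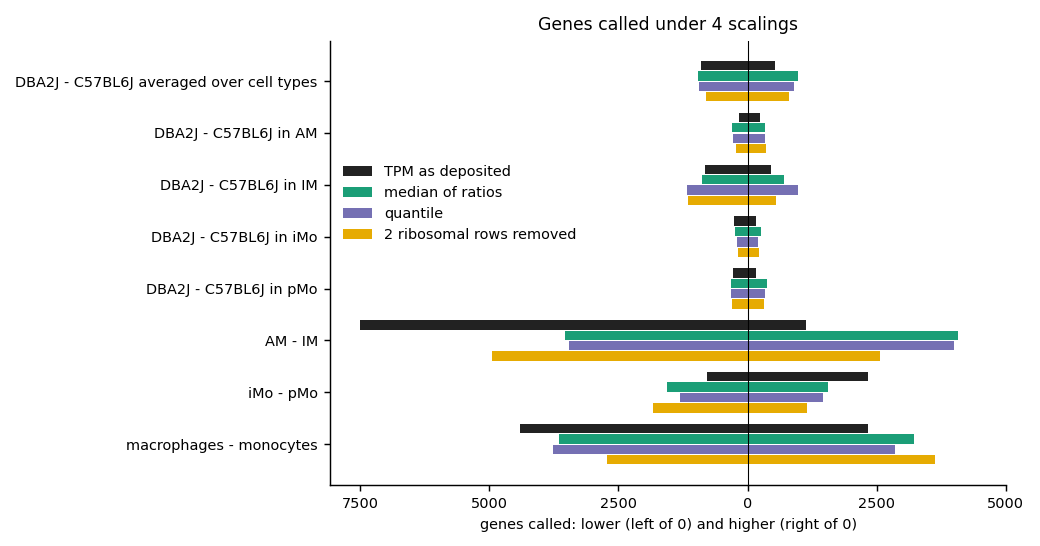
Number of genes called per contrast, lower to the left and higher to the right of 0, with TPM as deposited and 3 other scalings. AM minus IM has 1128 higher and 7496 lower as deposited, and 4064 higher and 3534 lower with median-of-ratios scaling.

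ATAC-seq marks open chromatin by the insertion of a transposase. The deposited peak sets held 32668 (AM), 70013 (IM), 35947 (iMo) and 45534 (pMo) peaks for C57BL6J and 43690, 24429, 32636 and 26592 for DBA2J, each made from 2 libraries, so that replicates could not be compared. Between strains, sets of the same cell type overlapped more than sets of different types, with a mean base-pair Jaccard index of 0.451 against 0.365. The difference of 0.086 was the largest of all 24 assignments of cell types to the DBA2J sets (exact one-sided permutation p = 0.0417, the smallest so few sets can give). By type the index was 0.517 in AM, 0.287 in IM, 0.562 in iMo and 0.436 in pMo. The DBA2J IM set overlapped the DBA2J iMo and pMo sets more (0.513 and 0.535) than the C57BL6J IM set (0.287). The number of peaks differed most between strains in IM, which limits that index. Between 12464 and 12546 peaks of each set overlapped a peak in all 8.

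**Figure D4:**
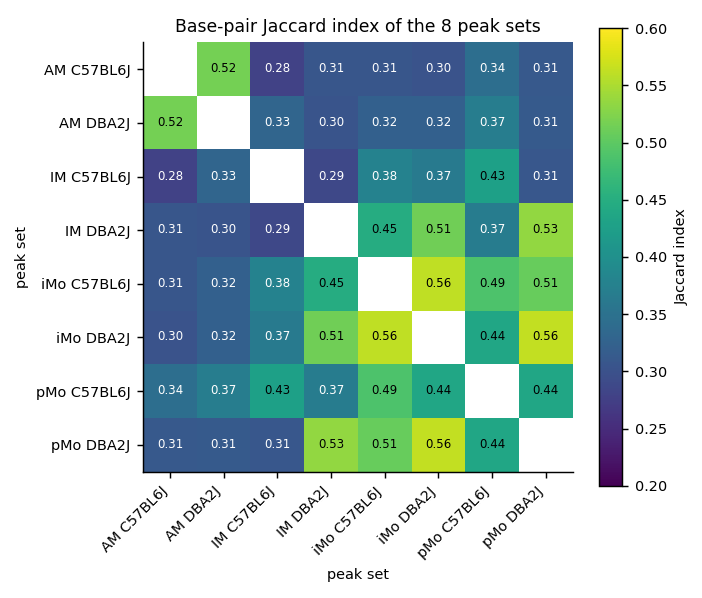
Base-pair Jaccard index between each pair of the 8 peak sets (rows and columns: cell type and strain; colour: index). The same cell type across strains gives 0.517 in AM, 0.287 in IM, 0.562 in iMo and 0.436 in pMo.

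Peaks found in both strains and in no other cell type numbered 3975 in AM, 429 in IM, 335 in iMo and 208 in pMo. The order of the last 3 depends on the number of peaks. With equal numbers of the strongest peaks the counts were 4143, 516, 579 and 555, and with the strongest 50% 2553, 116, 226 and 100. They lay away from promoters more often than the other peaks found in both strains, with 4.98%, 28.2%, 20.0% and 9.13% within 1 kb of a transcription start against 34.4%, 47.5%, 43.4% and 44.0%. With the strongest 50% the IM share was 46.6% against 65.4%. Of genes nearest to AM-specific peaks, 33.9% were higher in AM than in the mean of the other types, against 9.29% of other genes, and for IM, iMo and pMo the shares were 61.6% against 46.5%, 41.2% against 33.5% and 46.2% against 16.7%. More of the AM genes were lower than higher, 43.4% against 61.6% of other genes, and their median log2 difference was -0.17. The median of the other genes was -0.58. The majority of lower calls for AM against IM turned with median-of-ratios scaling (4064 higher, 3534 lower). Genes near peaks were compared with TPM as deposited only, so this excess of lower calls is not separated from the scaling. The lower shares were 2.86% against 6.58% for IM, 10.5% against 12.5% for iMo and 14.4% against 19.3% for pMo. The median log2 difference of these genes exceeded that of other genes by 0.41 for AM (1595 genes), 0.18 for IM (245), 0.00 for iMo (114) and 0.38 for pMo (104). With an estimated correlation camera called none (adjusted p = 0.606, 0.606, 0.885 and 0.606; unadjusted p from 0.196 to 0.885). At a preset correlation AM, IM and pMo passed (adjusted p = 5.3e-10, 0.00343 and 2.0e-04). Genes near peaks of only 1 strain did not differ in expression past the threshold in any type (camera with an estimated correlation, adjusted p = 0.897 for all 8 tests), while 4 of the 8 passed at a preset correlation. Against other genes, all 8 medians leaned to the strain with the peak. Near C57BL6J-only peaks 4.93%, 7.56%, 3.20% and 3.13% of genes (AM, IM, iMo, pMo) were lower in DBA2J. The shares of other genes were 1.03%, 4.85%, 1.88% and 1.61%. Near DBA2J-only peaks 3.46%, 8.87%, 1.97% and 3.76% were higher, against 1.25%, 3.72%, 1.19% and 1.27%. The failed test therefore does not show that strain peaks and expression are unrelated.

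Among the best-scored AM-specific peaks near a named gene, 1 of 6 assigned to Krt19 lay on mm10 chromosome 11 at 100149654 to 100149853, 6.05 kb from the transcription start and outside the transcript (432.5 TPM in AM). Another lay at 3339313 to 3339512 on chromosome 19, within the Cpt1a transcript, 16.1 kb from its start, and another near Cd209a (chromosome 8, 3754352 to 3754551), a gene at 0.197 TPM in AM and 42.2 in IM. IM-specific peaks lay 0.177 kb from the start of the prostaglandin synthase gene Ptgs2 (chromosome 1, 150100109 to 150100308; 22.9 TPM in IM and 0.038 in AM), at Fos (chromosome 12, 85474997 to 85475196, within the transcript) and near G0s2 (chromosome 1, 193275097 to 193275296). The iMo-specific ones lay near Irf5 (chromosome 6, 29524317 to 29524516) and at Slc12a2 (chromosome 18, 57878729 to 57878928). The pMo-specific ones lay within Msr1 (chromosome 8, 39619579 to 39619778), within Fpr2 (chromosome 17, 17890139 to 17890338) and at the start of Fabp4 (chromosome 3, 10208553 to 10208752), which averaged 37.7 TPM in pMo and 3.21 in iMo. Other genes were not highest in the type of their peak. Slc12a2 averaged 5.85 TPM in iMo and 54.6 in pMo, Msr1 8.45 in pMo and 33.3 in iMo, and Fpr2 28.8 in pMo and 63.8 in AM.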

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

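The tests of neutrophils among the sorted cells, of expression by IM, of C57BL6J-only peaks, of scaling and handling for immediate early genes, and of lost reads, near-identical copies and neighbours for shared strain differences, were chosen after the result was seen. Of 23 groups of 4 libraries examined for a library far from the others, 0 passed Dixon's limit at 95%. Chance alone would mark about 1 in 20. Each group mixed both strains, so a strain difference can widen its range and hide such a library. The count of 0 therefore does not show that no library stood apart. Closest to the limit was C1qa in IM, with a ratio of 0.828, just below it. There C57BL6J replicate 2 lay farthest from the others, at 1840 TPM, and the lowest IM library had 717.5 TPM. Of 63 genes named in a strain comparison, 30 had strain differences that themselves differed between the 4 cell types by limma's interaction test over all genes. Their adjusted p-values were Adgrg5 (1.3e-04), Alox15 (0.0163), Ccl3 (0.0123), Ccl4 (0.0210), Ccr1 (0.0153), Cd22 (1.7e-05), Cd74 (0.0211), Chil1 (1.6e-04), Cxcr4 (0.0188), F5 (0.00415), Folr2 (0.00306), Gpnmb (0.00435), H2-Aa (0.0291), H2-Ea-ps (3.6e-05), Hpgd (0.00262), Ifi202b (0.00117), Ifi213 (0.0102), Isg15 (0.0297), Kcne3 (1.3e-04), Mcoln3 (6.0e-05), Mmp12 (0.0139), Mndal (0.00712), Nlrp1c-ps (0.00250), Nov (4.8e-05), P2rx1 (5.0e-04), Rps2 (0.0367), Stab1 (0.0111), Stab2 (0.0157), Tlr5 (0.00205), Trim12a (0.0213). The genes were picked for large differences, some by that test itself, and over all genes it called 495 of 12277.

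Neutrophil genes stood high in all IM libraries. All 8 tested markers were higher in IM than in each other type. Of these, 7 of 8 lay above every other library in all 4 IM libraries, short of the 8 that the condition asked for. Neutrophils among the sorted cells, their free RNA and expression by IM would each raise these levels. Neither 7 nor 8 could therefore tell these sources apart. For free RNA of neutrophils the condition set beforehand was met, since 0 of 13 neutrophil genes had an IM-specific peak and 1 of 19 interstitial macrophage genes did. The further demand that the control list exceed other genes was added once that was known, and it changed the reading from agreement to undecided, because the control list did not exceed them either (Fisher's exact p = 0.253) and the DBA2J IM peak set is small. In C57BL6J alone, 12 of 13 neutrophil genes had an IM peak that overlapped no peak of another type, against 38.2% of all genes (Fisher's exact p = 8.0e-05). So did 9 of 10 endothelial genes (Fisher's exact p = 0.00113). Open neutrophil genes there argue against free RNA as the whole source in that strain. Expression of these genes by the IM themselves, with Ly6g at 1.12 TPM, stays open and cannot be told apart from such cells or RNA.

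Immediate early genes were lower in DBA2J. A difference in total or ribosomal share does not account for it, since with median-of-ratios scaling 9 of 21 were still called lower (12 as deposited), against 7.72% of other genes (Fisher's exact p = 1.3e-05). As deposited the list did not pass with an estimated correlation (adjusted p = 0.163 with an estimated correlation). The list median lay below that of other genes in 4 of 4 cell types (-0.27 in AM, -0.53 in IM, -0.55 in iMo and -0.55 in pMo). Handling that differed between the strains cannot be told apart from strain, since no label separates them, and a difference of strain is untested.

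Of the 68 genes that differed the same way in all 4 types, 44.1% were lower in DBA2J (two-sided exact binomial p = 0.396), which argues against reads lost against the C57BL6J reference as the source of the whole set. For the 30 lower genes such loss cannot be told apart from lower expression, since reads were not analysed here. Names of multicopy families or pseudogenes made up 23.5% of the set against 3.46% of tested genes (Fisher's exact p = 9.0e-10), but these families were picked after their names had been seen in the set. Reads shared between near-identical copies therefore cannot be told apart from strain for these 16 genes. The name rule left out other families with several members in the set. Among them Trim34a was lower and Trim34b higher in DBA2J in all 4 types. Shared reads were not examined for such genes, so the 16 are not a full count. Of the set, 35.3% had another member of the same direction within 1 Mb, above all 10000 random sets (highest 23.5%). Leaving out neighbours that overlap or share a family name it was 13.2%, which a share of 0.0589 of random sets reached, so clusters do not separate strain from handling. Apart from H2-Ea-ps, whose promoter deletion was known beforehand, handling that differed between the strains cannot be told apart from strain here, since no label separates them. Linked sequence differences between the strains remain an untested explanation.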

How the results depend on the processing

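Removal of the ribosomal entries, the second peak score, the narrower background for peaks, the fits without both C57BL6J IM libraries and the peak comparison without single RNA libraries were added after the data were seen, and every alternative chosen beforehand was run. Without the ribosomal entries the majority of calls turned from higher to lower for iMo against pMo (1141 higher, 1822 lower) and from lower to higher for macrophages against monocytes (3631 higher, 2728 lower). It turned from lower to higher for the strain difference in iMo (219 higher, 182 lower) and in pMo (316 higher, 294 lower) as well. Where a value moved the cause was not tested unless the alternative removes genes or libraries by construction. Depth is unknown, so how many low genes are missed cannot be given.

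With median-of-ratios scaling the counts were 646 (AM strain), 710 (pMo strain), 760 (interaction) and, for signatures, 914 (AM), 290 (IM) and 169 (pMo). With quantile normalization they were 610 (AM strain), 2162 (IM strain), 920 (interaction), 880 (AM signature) and 270 (IM signature), with 8 lists for the IM strain difference. Without the ribosomal entries they were 820 (interaction), 707 (AM signature) and 67 (iMo signature). With only the compared libraries in the fit, strain counts were 697 (AM), 61 (IM), 244 (iMo) and 156 (pMo), with 6 lists for pMo. A log2 difference of at least 1 left 360 (strain average), 824 (IM strain), 4575 (AM against IM), 1030 (iMo against pMo) and 2074 (macrophages against monocytes). C57BL6J libraries alone gave 1013 for iMo against pMo, and DBA2J libraries alone 1475, with 4467 for macrophages against monocytes and 73 iMo signature genes. Signatures without a fold minimum held 715, 1302, 851 and 286 genes. With a pseudocount of 5 they held 214 (AM), 240 (IM) and 84 (iMo), and with a minimum of 5 TPM 221 (AM) and 211 (IM). Without a filter the interaction gave 841.

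Lists past the test fell to 0 with an estimated correlation, except 1 for iMo against pMo. With fry they were 8 (AM), 9 (IM) and 3 (iMo) for strain, 17 for iMo against pMo and 23 for macrophages against monocytes. The IM strain difference had 9 lists with a pseudocount of 0.1, without a filter and with a minimum of 5 TPM, which also left 5 for the strain average and 3 for iMo. Without a filter pMo had 7. With fry the lysosome (adjusted p = 0.330) and oxidative phosphorylation (0.612) pointed down for AM against IM, and without IM C57BL6J replicate 2 the patrolling markers pointed down for the IM strain difference (adjusted p from 8.9e-06 to 0.989 over the fits without 1 library).

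Leaving out 1 library assumes that the lone sample varies like the other groups. Counts then ranged over 1029 to 1759 (strain average), 186 to 440 (AM), 492 to 1724 (IM), 203 to 499 (iMo), 191 to 581 (pMo), 7751 to 8727 (AM against IM), 2135 to 3338 (iMo against pMo), 6007 to 6848 (macrophages against monocytes) and 239 to 833 (interaction). Lists ranged over 8 to 13, 10 to 18, 7 to 14, 2 to 10, 1 to 5, 16 to 20, 10 to 12 and 13 to 15 in the same order without the interaction. Signatures ranged over 341 to 397, 450 to 557, 115 to 165 and 95 to 156.

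With replicate number as a block the counts were 1401 (strain average), 378, 1204, 399 and 434 (AM, IM, iMo, pMo), 8635, 3057, 6716 and 458 (interaction), and no call count moved by over 1.5 times. The block was common to both strains, so it does not test pairing within a strain. At a preset correlation the differences near peaks passed for AM (0.41), IM (0.18), pMo (0.38) and, for strain, C57BL6J AM (-0.0773), DBA2J AM (0.0566), DBA2J IM (0.159) and DBA2J pMo (0.0896). The excess of peak overlap within cell types ran from 0.086 to 0.146 over 5 settings. Its exact permutation p was 0.0417 in each, which is its lowest possible value and so cannot show how firm the result is.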

Other observations

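No test in this part was chosen after its own count was seen, though the gene counts of the real groups were known. Comparing AM with IM, the real grouping gave 7850 genes called and 1 of 35 splits as many (the real one; highest other 34), and for iMo against pMo 1714 and 1 of 35 (highest other 203). For lists it was 16 and 1 of 35 (highest other 12) for AM against IM, while for iMo against pMo 9 of 35 splits gave as many as the real 11 (highest other 16), so chance cannot be excluded for that number of lists. For macrophages against monocytes 2 of 100 splits gave as many genes as the real 3044, and the highest other, 3855, set all AM against all IM libraries, with most pMo beside the AM and most iMo beside the IM. That split follows the structure of the cell types. The number of lists, 13, was reached by 10 of 100 (highest other 16), and chance cannot be excluded. For strain, split within cell types, 872 genes were reached by 1 of 100 (highest other 280), and the 10 lists by 24 of 100 (highest other 15), so chance cannot be excluded for the lists. These are fits of 2 groups, so their counts differ from those of the full model. Every other split of AM with IM, or of iMo with pMo, mixes the types, so their difference enters the spread and few genes can be called. The low gene counts of those splits therefore add little to the calls themselves.

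For signatures, 1 of 100 splits gave as many genes as the real 343 of AM, 1 as the 442 of IM, 2 as the 113 of iMo and 2 as the 92 of pMo (highest other 312 in any group). Differences near type-specific peaks were reached by 1 of 100 splits in AM (0.410; highest other 0.283), 1 in IM (0.181; highest other 0.142), 47 in iMo (0.00174; highest other 0.0978) and 3 in pMo (0.379; highest other 0.425). For the iMo peaks chance cannot be excluded, and camera with an estimated correlation called none of these sets of genes. Splits that mix cell types blur the differences between types. Low counts of splits therefore add little to the signatures and to the AM, IM and pMo peaks.

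Of eosinophil and mast cell genes, 2 passed the filter. The summed level of the 10 in the table ran from 112.7 to 244.4 TPM in AM and from 0.226 to 1.32 TPM in iMo. Most of the AM sum was Siglecf, which is also an alveolar macrophage marker and a sort panel gene. It averaged 118 TPM in DBA2J AM and 239 in C57BL6J AM, against 1.49 and 0.202 for Kit. The AM sum therefore does not measure eosinophils or mast cells.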
